A study of Mus musculus with 18 samples.

How the data were processed

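Gene expression was measured by RNA sequencing in 18 libraries of conventional dendritic cells (cDC) from mouse spleen. They fall into 6 groups of 3 libraries, given by genotype (wild type, WT, or ADAM10-deficient, KO) and by sorted population. Per the labels' protocols, spleens were digested with collagenase and DNase, cells carrying CD11c were enriched on magnetic columns, and living cells positive for CD11c and MHC class II were sorted into CD8+ cDC1, CD4+ cDC2 and CD4-CD8- cDC2. Poly(A) RNA was selected, converted to libraries and sequenced as single-end reads, per the same protocols. The labels do not describe how ADAM10 was removed.

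The submitters' processing notes name FastQC 0.11.8, Salmon 0.14.1 and the genome build GRCm38. The deposited values come as a pair of tables at transcript level for the whole series. One holds the authors' estimated counts per transcript (117135 transcripts), with fractional values, as Salmon divides reads among similar transcripts. The other holds TPM as the authors deposited them (84086 transcripts), which are scaled within each library for transcript length and total. Totals of estimated counts ran from 12358884 to 19557469 per library. Estimated counts of near-identical genes depend on how Salmon divided shared reads, so values of paralogs such as Lyz1 and Lyz2, Mgl2 and Clec10a, or the alpha globins carry that uncertainty. The labels do not say whether strand was used, so overlapping genes on opposite strands cannot be told apart.

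Transcripts were summed per gene with the gene names in the tables. Of 152 transcripts without a gene, 37 were filled from the GENCODE M21 annotation, in which 99.0% of the transcript identifiers were found, and 115 were left out (at most 0.16% of a library's counts). The 24614 gene sums were rounded to whole counts. Genes were filtered with filterByExpr of edgeR 4.0.16 under R 4.3.3, which left 13381 genes, and the counts were scaled by TMM. Gene positions are those of GRCm38 in GENCODE M21. CPM were computed from TMM-scaled library sizes.

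A negative binomial model with 1 mean per group was fitted to all 18 libraries (12 residual degrees of freedom), and edgeR's quasi-likelihood F test was used for every comparison, two-sided, with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05, and "rose" and "fell" are used for called genes. The standard error of a log2 fold change was taken from its F statistic. The comparisons were KO minus WT within each population, the 3 differences between these effects (interactions), and the 3 differences between populations in WT. The labels number the libraries of each group 1 to 3 but do not say that these came from separate animals, so p-values measure the spread between these libraries, which may be technical in part. For 18 pairs of libraries of the same group, the chi-square per gene was 11.0 to 39.0, which is more spread than counting error alone would leave.

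Gene lists were fixed before the data were examined. There were 38, of which 37 had at least 3 tested genes. They covered Notch targets, Notch receptors and modifiers, genes typical of ESAM-high and of ESAM-low cDC2, cDC1, cDC2 and pan-cDC genes, and DC maturation. Further lists held MHC class II and class I presentation, interferon-stimulated genes, inflammatory mediators, immediate early genes, cell cycle, unfolded protein response, cholesterol synthesis, LXR targets, ADAM proteases with their partners, reported ADAM10 substrates, migration receptors, Toll-like and C-type lectin receptors, oxidative phosphorylation and glycolysis. Marker lists stood for B cells, plasma cells, T cells, NK cells, pDC, monocytes, red pulp macrophages, marginal zone macrophages, neutrophils, erythroid cells, platelets, mast cells and basophils, and stromal and endothelial cells. RNA quality was followed with mitochondrially encoded genes and ribosomal protein genes. Each list was tested against all other genes with camera in limma 3.58.1, with a preset correlation of 0.01 between genes, and adjusted over all 111 list tests. Camera with an estimated correlation was run beside it. Members called were also counted with the p-values adjusted over the list alone. In 11 of the 111 tests the median of the list and camera's direction had opposite signs, and 0 of these 11 tests passed (lowest adjusted p 0.331). Symbols that 2 gene identifiers share were counted once per identifier.

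The genes named in the text were chosen by a rule that was fixed together with the lists. It took Adam10, the 10 genes with the largest rise and the 10 with the largest fall per population, up to 4 called members of each list, 20 genes always reported, and 5 genes per direction for each interaction and each WT difference. Genes ranked by size had to reach a mean of 5 CPM in the higher group, and the replicates of the compared groups were not to overlap, which was not asked of interactions. One gene that met this rule is not reported here. Predicted genes, pseudogenes, antigen receptor segments and Y-linked genes were passed over. The sort used CD4, CD8, CD11c and MHC class II, so differences of Cd4, Cd8a, Itgax or MHC class II genes between populations are no findings.

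Replicate numbers were checked for pairing by correlating the residuals of same-numbered libraries across genes. Between WT and KO libraries of 1 population, some correlations lay at or below 0.1 (lowest -0.19, in CD4+ cells), so the numbers were not taken as pairs for KO minus WT. Within each genotype, same-numbered libraries of CD4+ and CD8+ cells correlated between 0.219 and 0.367 in WT and between 0.227 and 0.29 in KO, and those of CD4-CD8- and CD8+ cells between 0.176 and 0.288 in WT and between 0.354 and 0.409 in KO. Numbers therefore pair the libraries in those interactions, and the pairing comes from the data, as no label explains the numbers. For CD4+ and CD4-CD8- cells the lowest correlation was 0.196 in WT and 0.0126 in KO.

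The fit was tested on simulated counts before use. For KO minus WT in CD4+ cells, 43.8% of genes simulated with a 1.5-fold change were called, 79.2% with a 2-fold, 77.6% with a 4-fold and 91.8% with an 8-fold change. Of the 147 calls over 13136 genes, 5 were unchanged genes (3.40%). Over 13155 simulated genes with 35 lists, only the shifted list was called. Genes were drawn independently of each other there, so the simulation could not show how correlation between genes affects the list test.

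Alternatives were scaling by DESeq2 size factors, the Wald test of DESeq2 1.42.0, limma on log2(TPM + 1) and on log2(TPM + 0.1), no filter on low counts, a filter of 5 CPM in 3 samples, an offset for average transcript length, replicate blocks, protein-coding genes only, fits on the compared groups only, and leaving out each library in turn. Chosen after the data were seen were an NK and T cell marker score as covariate, leaving out the 3 WT libraries numbered 3, and limma on TMM-scaled TPM. A fold change against a group without any count is given as a lower bound against a floor of 3 counts over the group. That floor covers counting error only, and PCR copies are not independent molecules. Only filtered genes and the 115 transcripts without a gene were left out of the comparisons. Figures were drawn with matplotlib 3.10.9.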

Results

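RNA was sequenced from splenic cDC of wild-type (WT) and ADAM10-deficient (KO) C57BL/6 mice. ADAM10 is a membrane protease that cuts Notch receptors and other surface proteins. The 18 libraries fall into 6 groups of 3, which are CD4+ cDC2, CD4-CD8- cDC2 and CD8+ cDC1 of each genotype, all sorted as living CD11c+MHCII+ cells. After filtering, 13381 genes were tested. The first principal component (45.8% of the variance) set CD8+ cells apart from the others, and the second (15.3%) separated the genotypes.

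Ribosomal protein genes took 8.93% ± 0.152 of the counts in WT and 10.1% ± 0.504 in KO CD4+ cells (SD, n = 3), 8.25% ± 0.556 and 10.0% ± 0.174 in CD4-CD8- cells, and 8.86% ± 0.0658 and 10.5% ± 0.564 in CD8+ cells. The 10 most abundant genes held 10.6% of the counts in WT and 14.7% in KO CD4+ cells, 9.84% and 13.2% in CD4-CD8- cells, and 12.6% and 14.1% in CD8+ cells. Mitochondrially encoded genes took between 1.85% and 2.12% of the counts in every group on average. All log2 fold changes below are given with the standard error of the edgeR quasi-likelihood fit (n = 3 libraries per group) and a Benjamini-Hochberg adjusted p. Counts "over the list alone" are calls with p adjusted within that list. The "estimated" value of a list is its camera adjusted p with an estimated correlation between genes.

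Adam10 RNA was lower in KO than in WT cells of every population. The gene (ENSMUSG00000054693.14) lies on the plus strand of chromosome 9 from 70678997 to 70780229 in GRCm38. WT CD4+ libraries held 82.85, 80.55 and 129.5 CPM and KO CD4+ libraries 41.8, 41.6 and 45.9 CPM. The group means were 97.6 ± 27.6 and 43.1 ± 2.40 CPM (SD, n = 3), a log2 fold change of -1.18 ± 0.22, adjusted p 5e-04. In CD4-CD8- cells WT libraries held 90.9, 88.3 and 138 CPM and KO libraries 47.45, 41.7 and 44.6 CPM (means 105.9 ± 28.2 and 44.6 ± 2.89), with a log2 fold change of -1.25 ± 0.22, adjusted p 0.000552. In CD8+ cells the values were 57.0, 58.3 and 98.97 CPM in WT and 28.7, 31.0 and 36.4 CPM in KO (means 71.4 ± 23.9 and 32.1 ± 3.98), with a log2 fold change of -1.15 ± 0.23, adjusted p 0.00187. In each population the WT library numbered 3 was the highest. The labels do not give the deletion strategy, and Salmon assigns reads to whole transcripts, so the files cannot show which part of the gene is missing.

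**Figure D1:**
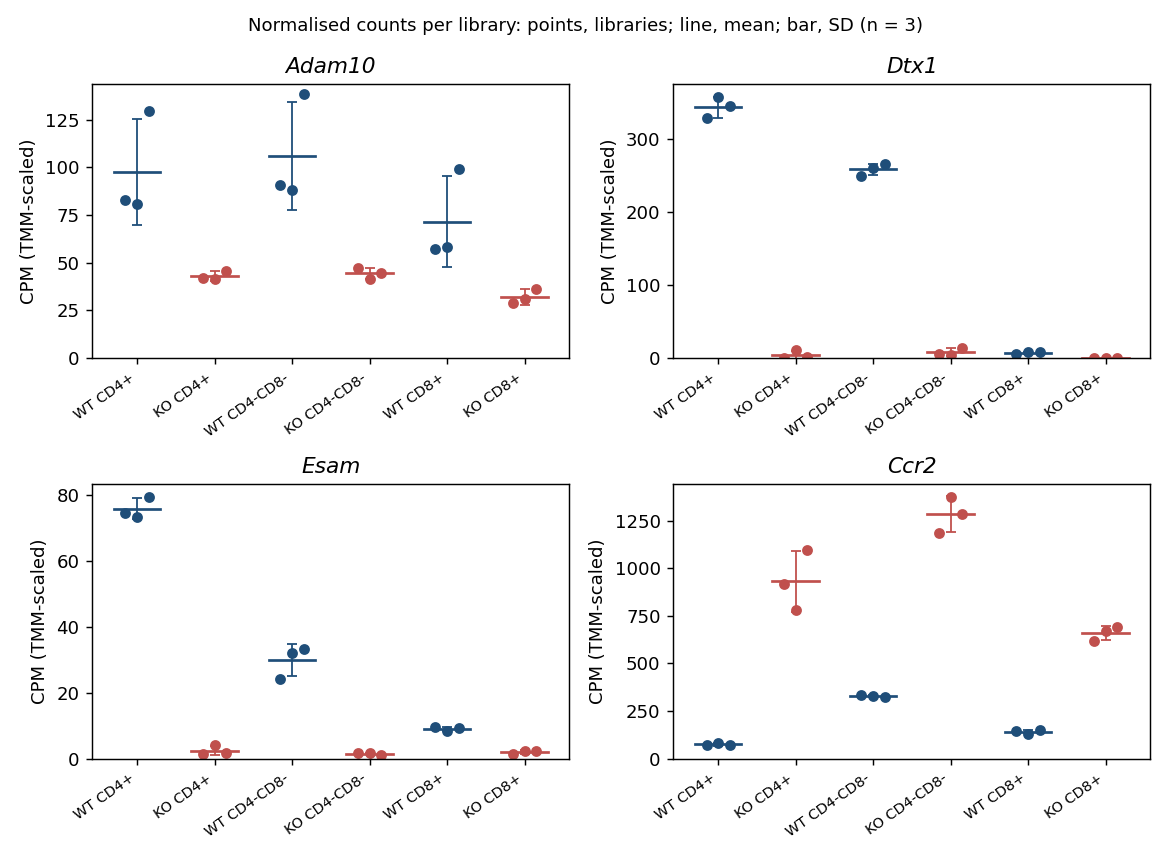
CPM of Adam10, Dtx1, Esam and Ccr2 on linear axes, with each point 1 library of the 6 groups of 3, and mean and SD as line and bar. Every KO library held less Adam10 than every WT library of its population, and mean Dtx1 fell from 343 to 4.54 CPM in CD4+ cells.

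The comparison of KO with WT CD4+ cDC2 asked what ADAM10 deficiency changes in the population that depends on Notch2 signalling. Dtx1, an E3 ligase gene induced by Notch, fell from 343 ± 14.5 to 4.54 ± 5.53 CPM (SD, n = 3), a log2 fold change of -6.21 ± 0.58, adjusted p 3.75e-07. Dtx1 (ENSMUSG00000029603.15) lies on the minus strand of chromosome 5 from 120680202 to 120711927 in GRCm38. Hes1, a repressor gene directly switched on by Notch, fell (log2 -4.98 ± 0.43, adjusted p 1.43e-07). Esam, an adhesion molecule that marks Notch-dependent cDC2, fell from 75.9 ± 3.18 to 2.42 ± 1.46 CPM (log2 -4.95 ± 0.27, adjusted p 1.22e-09). Fcrls, an Fc receptor-like scavenger receptor of macrophages, rose from 0.142 ± 0.153 to 237 ± 75.2 CPM (log2 10.50 ± 0.69, adjusted p 6.96e-09). Fn1, which encodes fibronectin, rose from 0.984 ± 0.555 to 200.3 ± 74.8 CPM (log2 7.64 ± 0.50, adjusted p 7.27e-09).

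In all, 4692 genes passed in CD4+ cells, 2476 higher and 2216 lower in KO, of which 943 and 611 changed at least 2-fold. On TPM scales or with a length offset 2838 to 3098 passed. Lpl, which encodes lipoprotein lipase, rose (log2 5.42 ± 0.31, adjusted p 1.79e-09). F13a1, a clotting factor chain made by monocytes and macrophages, rose (log2 6.25 ± 0.42, adjusted p 8.44e-09). Cxcl13, a chemokine that attracts B cells, rose (log2 6.38 ± 0.58, adjusted p 2.47e-07). Il1rl1, the receptor for IL-33, rose (log2 7.41 ± 0.54, adjusted p 1.89e-08), and Dok2, an adaptor of kinase signalling (log2 6.66 ± 0.45, adjusted p 8.68e-09). Among large falls, Mmp9, a gelatinase, was at -6.09 ± 0.35, adjusted p 1.96e-09. Cdh17, a cadherin, was at -5.75 ± 0.60, adjusted p 1.2e-06, and Gp2, a receptor for bacterial fimbriae, at -6.01 ± 0.64, adjusted p 3.54e-06. Blk, a kinase of the Src family, was at -5.50 ± 0.31, adjusted p 1.54e-09, and Abcb1a, a drug efflux pump, at -5.55 ± 0.38, adjusted p 9.32e-09.

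Among Notch targets in CD4+ cells, 2 rose, 3 fell and 4 did not pass of 9 tested (2 and 3 over the list alone), and the list as a whole did not pass (camera adjusted p = 0.523). Nrarp, a feedback inhibitor of Notch, fell (log2 -2.46 ± 0.67, adjusted p 0.00813), while Il2ra, the alpha chain of the IL-2 receptor, rose (log2 1.99 ± 0.32, adjusted p 0.000129). Notch1 rose on counts (log2 1.76 ± 0.17, adjusted p 3.64e-07), but on TPM with a pseudocount of 1 its log2 was 1.07 at an adjusted p of 0.289. Of the Notch receptors and modifiers 4 rose, 2 fell and 13 did not pass of 19 tested (4 and 2 over the list alone; camera adjusted p = 0.787). Notch2, the receptor needed by these cells, rose (log2 0.51 ± 0.11, adjusted p 0.00156, but 0.32 at an adjusted p of 0.126 on TPM). Dtx2 also rose (log2 1.18 ± 0.07, adjusted p 2.14e-09). Notch4 (log2 -2.44 ± 0.31, adjusted p 1.22e-05) and the ligand gene Jag1 (log2 -1.14 ± 0.20, adjusted p 0.000257) fell.

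Genes of ESAM-high cDC2 fell and those of ESAM-low, monocyte-like cDC2 rose. Of the ESAM-high list 0 rose, 6 fell and 2 did not pass of 8 tested (0 and 6 over the list alone, camera adjusted p = 0.00189, 0.102 estimated), with a median log2 of -1.96. Clec4a4, the lectin recognised by the antibody 33D1, fell (log2 -2.56 ± 0.15, adjusted p 1.86e-09), and Cd4 was at log2 -0.03 ± 0.17, adjusted p 0.906. Of the ESAM-low list 13 rose, 0 fell and 0 did not pass of 13 tested (13 and 0 over the list alone, camera adjusted p = 5.59e-11, 0.0926 estimated), with a median log2 of 2.19. Ccr2, the receptor that leads monocytes out of bone marrow, rose from 74.2 ± 6.19 to 931 ± 159 CPM (log2 3.65 ± 0.12, adjusted p 4.19e-12). Cx3cr1, the fractalkine receptor, rose from 76.4 ± 7.49 to 409 ± 37.5 CPM (log2 2.42 ± 0.20, adjusted p 7.54e-08). The lectins Clec10a (log2 5.03 ± 0.25, adjusted p 3.36e-10) and Mgl2 (log2 5.01 ± 0.28, adjusted p 1.22e-09) rose as well.

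Of the red pulp macrophage markers 10 rose, 1 fell and 3 did not pass of 14 tested (10 and 2 over the list alone, camera adjusted p = 0.0016, 0.524 estimated), with a list median of 1.82. Mrc1, the mannose receptor (log2 5.18 ± 0.34, adjusted p 6.42e-09), and Cd163, the haemoglobin scavenger receptor (log2 3.36 ± 0.42, adjusted p 8.98e-06), rose. Of the monocyte markers 9 rose, 5 fell and 2 did not pass of 16 tested (9 and 5 over the list alone; camera adjusted p = 0.162). The lysozyme genes Lyz1 (log2 4.57 ± 0.19, adjusted p 7.27e-11) and Lyz2 (log2 2.67 ± 0.14, adjusted p 7.53e-10) rose, and Plac8 fell (log2 -2.41 ± 0.15, adjusted p 4.4e-09). T cell markers gave 4 rises and 0 falls among 13 tested (4 and 0 over the list alone, camera adjusted p = 0.022, 0.598 estimated), with a mean from 1.40 to 3.29 CPM. The T cell list did not pass without KO CD4+ library 3 (adjusted p = 0.0688). Of the ribosomal protein genes 22 rose, 0 fell and 11 did not pass of 33 tested (24 and 0 over the list alone, camera adjusted p = 3.62e-05, 0.538 estimated).

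Genes of the cell cycle fell in KO CD4+ cells, where 0 rose, 29 fell and 2 did not pass of 31 tested (0 and 29 over the list alone) and the list median was -1.02. For the cell cycle list the camera adjusted p was 1.19e-12 (0.44 estimated). Mcm5, part of the replicative helicase, fell (log2 -1.06 ± 0.10, adjusted p 5.16e-07), and Pcna, the sliding clamp of DNA polymerase, fell (log2 -0.72 ± 0.07, adjusted p 8.22e-07). Of the genes for MHC class II presentation 8 rose, 4 fell and 1 did not pass of 13 tested (8 and 4 over the list alone, camera adjusted p = 0.0193, 0.48 estimated). H2-DMa, a peptide exchange factor (log2 0.99 ± 0.08, adjusted p 6.22e-08), and Cd74, the invariant chain (log2 0.81 ± 0.07, adjusted p 7.6e-08), rose. Among the ADAM proteases and their partners 11 rose, 4 fell and 5 did not pass of 20 tested (11 and 4 over the list alone, camera adjusted p = 0.0184, 0.188 estimated). The protease gene Adam15 (log2 2.95 ± 0.12, adjusted p 4.87e-11) and the ADAM10 chaperone gene Tspan5 (log2 1.39 ± 0.12, adjusted p 1.68e-07) rose, and Adam8 fell (log2 -1.10 ± 0.11, adjusted p 7.49e-07). For reported ADAM10 substrates 13 rose, 5 fell and 5 did not pass of 23 tested (13 and 5 over the list alone, camera adjusted p = 0.0371, 0.532 estimated). The substrate list did not pass without WT CD4+ library 2 (adjusted p = 0.0603) or KO CD4+ library 3 (adjusted p = 0.0510). Cxcl16, a membrane-bound chemokine, rose (log2 1.10 ± 0.16, adjusted p 4.56e-05), and Havcr2, which encodes TIM-3, fell (log2 -2.37 ± 0.13, adjusted p 1.36e-09). For unfolded protein response genes 9 rose, 1 fell and 10 did not pass of 20 tested (11 and 1 over the list alone, camera adjusted p = 0.0131, 0.538 estimated). The chaperone gene Hsp90b1 rose (log2 0.99 ± 0.12, adjusted p 5.96e-06).

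Of the cDC2 list 7 rose, 6 fell and 6 did not pass of 19 tested (8 and 6 over the list alone; camera adjusted p = 0.811). Of the cDC1 list 7 rose, 4 fell and 6 did not pass of 17 tested (7 and 4 over the list alone; camera adjusted p = 0.391). Of the pan-cDC list 4 rose, 3 fell and 4 did not pass of 11 tested (4 and 5 over the list alone; camera adjusted p = 0.636). Itgam, the integrin CD11b, rose (log2 1.02 ± 0.17, adjusted p 0.000167). So did Irf8, a transcription factor of cDC1 (log2 0.65 ± 0.15, adjusted p 0.00205, but 0.28 at an adjusted p of 0.0987 on TPM), and Clec9a, a receptor for dead cells (log2 0.78 ± 0.13, adjusted p 0.000174). Zbtb46, a transcription factor of cDC, fell (log2 -0.57 ± 0.07, adjusted p 1.47e-05). Sirpa was at log2 0.16 ± 0.17, adjusted p 0.524 and Irf4 at -0.36 ± 0.16, adjusted p 0.104, which passed with a replicate block by number (adjusted p = 0.0440) and in a fit on CD4+ cells only (adjusted p = 0.0259). Itgax was at 0.11 ± 0.10, adjusted p 0.451 and Cd8a at 0.10 ± 0.23, adjusted p 0.796. Xcr1, the chemokine receptor of cDC1, was at log2 0.81 ± 0.30, adjusted p 0.0484. Of the fits without 1 CD4+ library, 5 of 6 ended its call, with the highest adjusted p (0.252) without KO library 2. It also missed the threshold on TPM (log2 0.27, adjusted p = 0.356), with the length offset (0.86, 0.0612), with the NK and T cell marker score as a covariate (0.86, 0.0558) and in a fit on CD4+ cells only (0.81, 0.0663). Expression of the DC maturation genes went both ways (8 rose, 10 fell and 7 did not pass of 25 tested; camera adjusted p = 0.65).

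The same comparison was made in CD4-CD8- cDC2. Dtx1 fell from 258 ± 7.92 to 8.06 ± 5.67 CPM (log2 -5.01 ± 0.55, adjusted p 5.9e-06), Hes1 fell (log2 -3.60 ± 0.41, adjusted p 7.49e-06) and Esam (log2 -4.30 ± 0.29, adjusted p 3.72e-08). Fcrls rose from 0.266 ± 0.308 to 244 ± 116 CPM (log2 9.71 ± 0.65, adjusted p 3.69e-08) and Lyz1 rose from 43.8 ± 4.95 to 1183 ± 287 CPM (log2 4.76 ± 0.20, adjusted p 4.84e-10). Lpl (log2 4.59 ± 0.30, adjusted p 3.11e-08), Fn1 (log2 4.57 ± 0.39, adjusted p 4.51e-07) and Mgl2 (log2 3.93 ± 0.26, adjusted p 3.54e-08) were other large rises. Cdh17 (log2 -5.81 ± 0.64, adjusted p 6.71e-06) and Hic1, a zinc finger repressor gene (log2 -4.88 ± 0.57, adjusted p 1.12e-05) were other large falls. In all, 3471 genes passed, 1953 higher and 1518 lower, of which 422 and 578 changed at least 2-fold. With the offset or on TMM-scaled TPM 2179 and 2166 passed.

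Notch targets fell as a list in CD4-CD8- cells, where 0 rose, 5 fell and 4 did not pass of 9 tested (0 and 6 over the list alone) and the median was -1.70. For the Notch target list the camera adjusted p was 0.00243 (0.108 estimated). Heyl, another Notch-induced repressor gene, fell (log2 -3.21 ± 0.80, adjusted p 0.00801, but -3.02 at an adjusted p of 0.187 with an offset for transcript length). Nrarp was at log2 -1.70 ± 0.60, adjusted p 0.0476, a call that 5 of the 6 fits without 1 library ended, with the highest adjusted p (0.165) without WT library 1. Notch1 was at -0.35 ± 0.15, adjusted p 0.0973, and at an adjusted p of 0.0342 without KO library 3. Of the Notch receptors and modifiers 3 rose, 4 fell and 12 did not pass of 19 tested (3 and 4 over the list alone; camera adjusted p = 0.667). Notch2 (log2 0.52 ± 0.11, adjusted p 0.00201, but 0.22 at an adjusted p of 0.283 on TPM) and Rbpj, the DNA-binding partner of Notch (log2 0.94 ± 0.13, adjusted p 6.3e-05), rose. The ligand gene Dll1 fell (log2 -3.21 ± 0.53, adjusted p 0.000289). The ESAM-high list gave 0 rises and 6 falls among 8 tested (0 and 6 over the list alone, camera adjusted p = 0.000393, 0.0821 estimated). Clec4a4 (log2 -2.36 ± 0.15, adjusted p 2.77e-08) and Tbx21, which encodes T-bet (log2 -2.07 ± 0.42, adjusted p 0.00142), fell. The ESAM-low list gave 11 rises and 0 falls among 13 tested (11 and 0 over the list alone, camera adjusted p = 1.13e-09, 0.108 estimated). Ccr2 rose from 328 ± 5.44 to 1282 ± 94.0 CPM (log2 1.97 ± 0.11, adjusted p 6.11e-09), and Cx3cr1 (log2 1.33 ± 0.19, adjusted p 7.08e-05).

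Transcripts of NK and T cells fell in KO CD4-CD8- cells. Of the NK cell markers 0 rose, 9 fell and 2 did not pass of 11 tested (0 and 9 over the list alone, camera adjusted p = 1.07e-05, 0.44 estimated), with a mean from 79.4 to 21.3 CPM and a median log2 of -2.81. Klra8, an NK receptor (log2 -3.56 ± 0.37, adjusted p 7.46e-06), and Klre1, another NK receptor (log2 -3.09 ± 0.32, adjusted p 3.69e-06), fell. So did Eomes, a transcription factor of NK cells (log2 -3.06 ± 0.44, adjusted p 8.7e-05). Of the T cell markers 0 rose, 11 fell and 2 did not pass of 13 tested (0 and 13 over the list alone, camera adjusted p = 3.31e-06, 0.44 estimated), with a mean from 24.1 to 5.18 CPM. Cd247, the zeta chain of the T cell receptor complex (log2 -2.55 ± 0.45, adjusted p 0.000535), and Bcl11b (log2 -3.30 ± 0.65, adjusted p 0.00117) fell. B cell markers gave 0 rises and 5 falls among 13 tested (1 and 6 over the list alone; camera adjusted p = 0.0583), with Blk at log2 -3.82 ± 0.31, adjusted p 2.25e-07. The B cell list passed without WT library 1 (adjusted p = 0.0351), KO library 2 (adjusted p = 0.0253) or KO library 3 (adjusted p = 0.0234). With a score of NK and T cell markers as a covariate, 934 genes passed in this population in place of 3471. The score nearly labels the 2 groups, so a lost call may come from a wider error. Calls ended for Klra8 (log2 -2.11, adjusted p = 0.0795), Eomes (-1.24, 0.367), Cd247 (-0.24, 0.886) and Bcl11b (-1.34, 0.503), which decides nothing, as such markers form the score. They also ended for Xcr1 (log2 1.07, adjusted p = 0.145), Clec9a (0.65, 0.0974), Cxcl16 (0.39, 0.396), Dll1 (-1.97, 0.232), Heyl (-0.89, 0.868), Tbx21 (-0.90, 0.531), Mcm2 (-0.65, 0.0639), Itgam (1.04, 0.0816), Notch2 (0.44, 0.187), Irf8 (0.53, 0.264) and Nrarp (-1.47, 0.539).

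**Figure D2:**
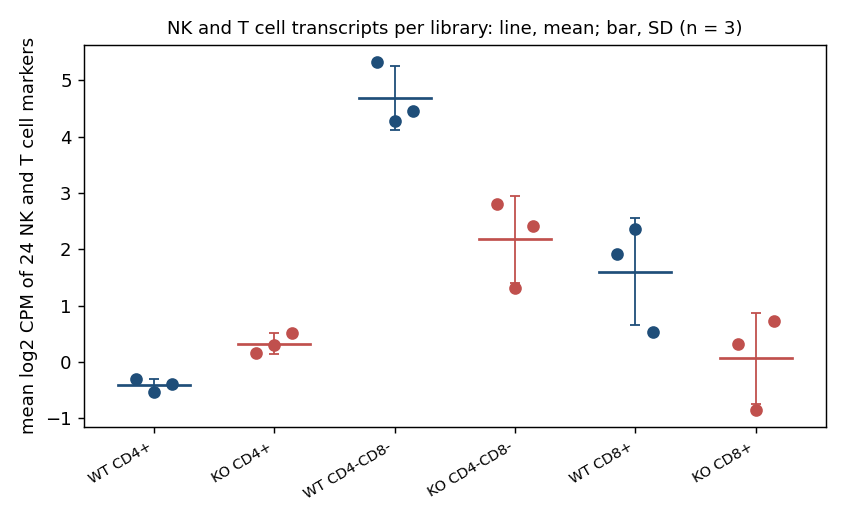
Mean log2 CPM of 24 NK and T cell markers, with each point 1 library of the 6 groups of 3, and mean and SD as line and bar. In CD4-CD8- cells the values ran from 4.28 to 5.32 in WT and from 1.31 to 2.81 in KO.

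Of the cell cycle genes in CD4-CD8- cells 0 rose, 21 fell and 10 did not pass of 31 tested (0 and 28 over the list alone, camera adjusted p = 3.02e-10, 0.524 estimated), with Mcm2 at log2 -0.73 ± 0.12, adjusted p 0.000219. For MHC class II presentation 8 rose, 2 fell and 3 did not pass of 13 tested (8 and 2 over the list alone, camera adjusted p = 6.01e-05, 0.131 estimated). H2-DMa was at 1.01 ± 0.08, adjusted p 1.6e-07 and Ctss, a protease that trims the invariant chain, at 0.89 ± 0.07, adjusted p 2.02e-07. Of the cDC1 list 9 rose, 2 fell and 6 did not pass of 17 tested (9 and 2 over the list alone, camera adjusted p = 0.0301, 0.538 estimated). The cDC1 list did not pass without KO library 2 (adjusted p = 0.0907). Xcr1 (log2 1.24 ± 0.23, adjusted p 0.000883) and Clec9a (log2 0.65 ± 0.13, adjusted p 0.00108) rose. For Toll-like and C-type lectin receptors 12 rose, 3 fell and 11 did not pass of 26 tested (13 and 4 over the list alone, camera adjusted p = 0.022, 0.532 estimated). The lectin Clec12a rose (log2 1.47 ± 0.15, adjusted p 2.05e-06). Of the ADAM proteases and partners 10 rose, 2 fell and 8 did not pass of 20 tested (13 and 2 over the list alone, camera adjusted p = 0.00391, 0.108 estimated), with Adam15 at 1.92 ± 0.11, adjusted p 1.02e-08. Unfolded protein response genes gave 7 rises and 0 falls among 20 tested (9 and 0 over the list alone, camera adjusted p = 0.00678, 0.538 estimated). Ribosomal protein genes gave 29 rises and 0 falls among 33 tested (30 and 0 over the list alone, camera adjusted p = 3.33e-12, 0.263 estimated).

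Other lists did not pass in CD4-CD8- cells. These were the cDC2 list (7 rises and 7 falls among 19 tested; camera adjusted p = 0.814), the pan-cDC list (2 rises and 1 fall among 11 tested; camera adjusted p = 0.523), and DC maturation (7 rises and 8 falls among 25 tested; camera adjusted p = 0.667). Nor did reported ADAM10 substrates (10 rises and 4 falls among 23 tested; camera adjusted p = 0.396), monocyte markers (8 rises and 5 falls among 16 tested; camera adjusted p = 0.0554) or red pulp macrophage markers (5 rises and 1 fall among 14 tested; camera adjusted p = 0.258). The monocyte list passed in 4 of the 6 fits without 1 library, with the lowest adjusted p (0.0199) without WT library 2. Itgam (log2 0.97 ± 0.17, adjusted p 0.000474, but 0.34 at an adjusted p of 0.0782 on TPM) and Cxcl16 (log2 0.82 ± 0.16, adjusted p 0.00117) rose. Irf8 was at log2 0.55 ± 0.14, adjusted p 0.00989, with an adjusted p of 0.0685 without WT library 2 and of 0.0681 without KO library 2, and on TPM 0.19 at an adjusted p of 0.233. Sirpa was at 0.26 ± 0.17, adjusted p 0.294 and Irf4 at 0.38 ± 0.16, adjusted p 0.102, which passed with a replicate block by number (adjusted p = 0.0419) and in a fit on CD4-CD8- cells only (adjusted p = 0.0184). Itgax was at 0.20 ± 0.10, adjusted p 0.173 and Cd8a at -0.24 ± 0.18, adjusted p 0.363. Zbtb46 was at 0.00 ± 0.07, adjusted p 0.983, and on TPM with a pseudocount of 1 at -0.31 (adjusted p = 0.0291). Cd4 was at -0.69 ± 0.24, adjusted p 0.0428. It lost its call in each of the 6 fits without 1 library (highest adjusted p 0.186, without KO library 1), and was at 0.17 on TPM with a pseudocount of 1.

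CD8+ cDC1 were compared in the same way, and the differences from cDC2 are tested by the interactions below. Gp2 fell from 42.3 ± 17.2 to 0.264 ± 0.126 CPM (log2 -7.27 ± 0.53, adjusted p 3.62e-07). Apol7c, which acts in antigen escape from endosomes, fell from 1086 ± 77.8 to 64.9 ± 7.91 CPM (log2 -4.06 ± 0.23, adjusted p 1.18e-08). Cx3cr1 fell from 49.3 ± 13.3 to 8.26 ± 2.81 CPM (log2 -2.57 ± 0.22, adjusted p 5.74e-07). So did Irf4, a transcription factor of cDC2 (log2 -2.36 ± 0.19, adjusted p 3.13e-07), and Sirpa, an inhibitory receptor of cDC2 and macrophages (log2 -2.06 ± 0.19, adjusted p 1.1e-06). Lyz2 rose from 162 ± 13.1 to 921 ± 97.3 CPM (log2 2.50 ± 0.14, adjusted p 1.18e-08), and Ccr2 rose from 141 ± 9.26 to 659 ± 38.3 CPM (log2 2.23 ± 0.11, adjusted p 3.59e-09). Cyp8b1, a hydroxylase of bile acid synthesis, rose from 4.36 ± 1.78 to 42.6 ± 3.83 CPM (log2 3.28 ± 0.32, adjusted p 6.01e-06). In all, 2099 genes passed, 938 higher and 1161 lower, of which 184 and 574 changed at least 2-fold. With the offset, the NK and T cell marker score as a covariate, on TMM-scaled TPM or without the WT libraries numbered 3, 1178 to 1395 passed.

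Several Notch-linked genes fell in KO CD8+ cells. Hes1 fell from 18.3 ± 3.06 to 1.72 ± 0.404 CPM (log2 -3.41 ± 0.42, adjusted p 2.62e-05) and Notch3 (log2 -4.34 ± 0.53, adjusted p 2.62e-05). Dtx1 fell from 6.99 to 0.479 CPM (log2 -3.82 ± 0.92, adjusted p 0.00837). WT CD4-CD8- cells held 258, so cDC2 in the WT gate may contribute. Dtx1 was at -3.90 (adjusted p 0.0612) with a length offset and -3.59 (0.0586) with the covariate. Esam was at log2 -2.19 ± 0.29, adjusted p 5.35e-05, but -2.65 (0.053) with the offset. Nrarp was at -0.33 ± 0.72, adjusted p 0.829. Of the Notch targets 0 rose, 3 fell and 6 did not pass of 9 tested (0 and 3 over the list alone; camera adjusted p = 0.0537). Of the Notch receptors and modifiers 2 rose, 5 fell and 12 did not pass of 19 tested (2 and 5 over the list alone; camera adjusted p = 0.401). Notch2 rose (log2 0.80 ± 0.11, adjusted p 8.6e-05) and Jag1 fell (log2 -1.40 ± 0.22, adjusted p 0.000297). Notch1 was at log2 0.00 ± 0.15, adjusted p 1 on counts and at 2.48 on TPM with a pseudocount of 1 (adjusted p = 0.0286). The ESAM-high list gave 0 rises and 4 falls among 8 tested (0 and 5 over the list alone, camera adjusted p = 3.84e-05, 0.0708 estimated), with Clec4a4 at -3.59 ± 0.31, adjusted p 7.89e-07. The ESAM-low list gave 4 rises and 6 falls among 13 tested (4 and 7 over the list alone; camera adjusted p = 0.0583), which passed as a list without WT library 2 (adjusted p = 0.0332) or KO library 3 (adjusted p = 0.0165).

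Genes of cDC2 and of DC maturation fell in KO CD8+ cells. Of the cDC2 list 1 rose, 13 fell and 5 did not pass of 19 tested (1 and 13 over the list alone, camera adjusted p = 3.02e-10, 0.0821 estimated), with a median log2 of -1.24, among them S100a4 (log2 -2.17 ± 0.16, adjusted p 2.06e-07). Of the maturation list 1 rose, 19 fell and 5 did not pass of 25 tested (2 and 20 over the list alone, camera adjusted p = 2.01e-12, 0.0708 estimated), with a median of -1.20. Ccr7, the receptor that guides DC to T cell zones, fell (log2 -2.19 ± 0.23, adjusted p 4.47e-06). Cd274, which encodes PD-L1, fell (log2 -2.28 ± 0.23, adjusted p 2.85e-06), and Il4i1, an amino acid oxidase (log2 -1.82 ± 0.11, adjusted p 2.14e-08). In the cDC1 list 5 rose, 1 fell and 11 did not pass of 17 tested (8 and 1 over the list alone, camera adjusted p = 0.00713, 0.532 estimated). Naaa, a lysosomal amidase gene, rose (log2 0.91 ± 0.15, adjusted p 0.000363) and Cd8a fell (log2 -0.85 ± 0.13, adjusted p 0.000291). Xcr1 (0.44 ± 0.22, adjusted p 0.221), Clec9a (0.24 ± 0.12, adjusted p 0.228) and Irf8 (0.35 ± 0.14, adjusted p 0.116) did not pass, though Irf8 did in a fit on CD8+ cells only (adjusted p = 0.0440). The pan-cDC list gave 0 rises and 3 falls among 11 tested (0 and 4 over the list alone; camera adjusted p = 0.331). Itgax, the integrin CD11c, was at -0.88 ± 0.10, adjusted p 1.49e-05 and Zbtb46 at 0.09 ± 0.07, adjusted p 0.454. Itgam was at -0.33 ± 0.26, adjusted p 0.453, Cd4 at -0.36 ± 0.24, adjusted p 0.373 and Cxcl16 at -0.04 ± 0.16, adjusted p 0.919.

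**Figure D3:**
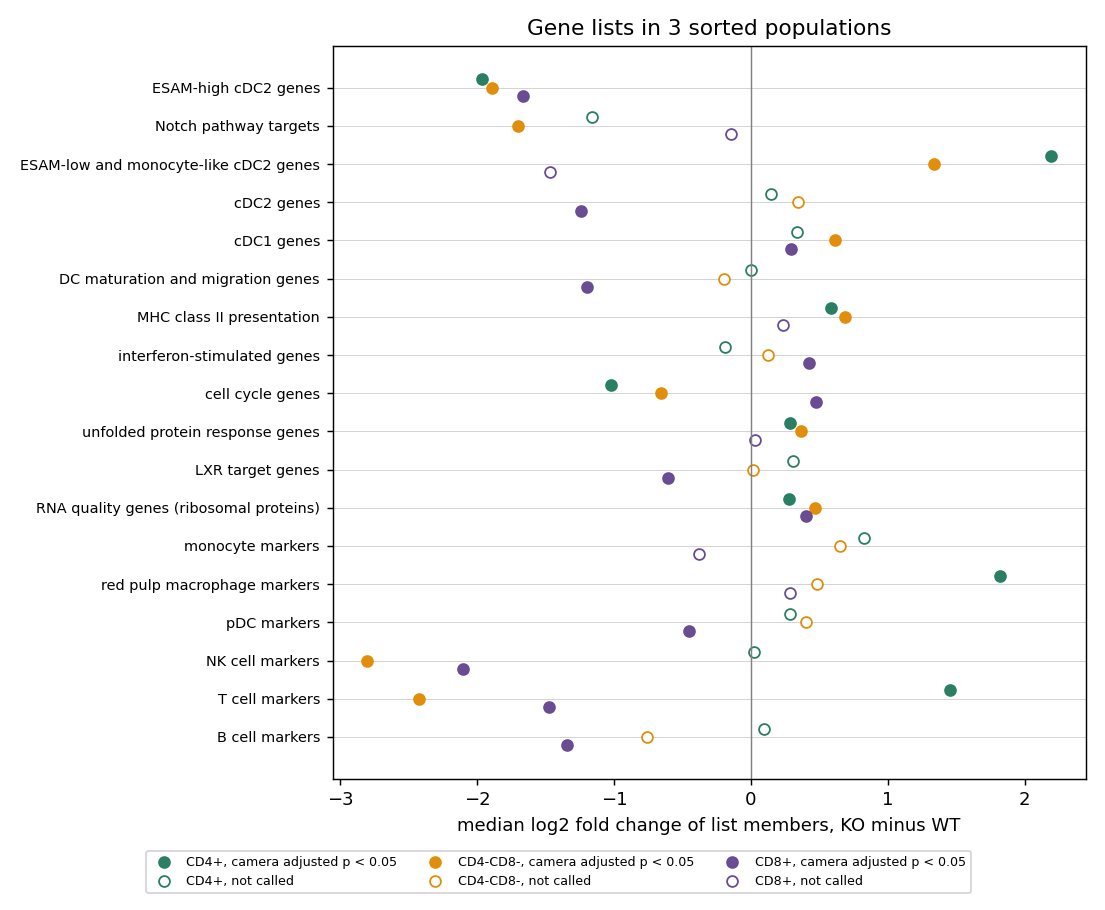
Median log2 fold change (KO minus WT) of 18 gene lists in the 3 populations, with filled markers where the camera adjusted p was under 0.05. The cell cycle list lay at -1.02 in CD4+ and at 0.48 in CD8+ cells.

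Of the interferon-stimulated genes in CD8+ cells 8 rose, 0 fell and 19 did not pass of 27 tested (11 and 0 over the list alone, camera adjusted p = 0.000146, 0.48 estimated), with a median of 0.43, among them Cmpk2 (log2 1.53 ± 0.12, adjusted p 3.47e-07) and Ifi27l2a (log2 1.57 ± 0.21, adjusted p 6.25e-05). Of the cell cycle genes 8 rose, 0 fell and 23 did not pass of 31 tested (9 and 0 over the list alone, camera adjusted p = 3.76e-05, 0.558 estimated). Of the ribosomal protein genes 25 rose, 0 fell and 8 did not pass of 33 tested (32 and 0 over the list alone, camera adjusted p = 1.82e-14, 0.188 estimated). LXR targets fell as a list (0 rises and 4 falls among 10 tested, 0 and 5 over the list alone). For the LXR list the camera adjusted p was 0.00447 (0.0926 estimated). Apoe, a carrier of lipids, was at -2.06 ± 0.33, adjusted p 0.000325.

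Lists of markers of other cells were tested in CD8+ cells too. B cell markers gave 1 rise and 5 falls among 13 tested (1 and 6 over the list alone, camera adjusted p = 0.0184, 0.538 estimated), with Cd79b, a chain of the B cell receptor, at log2 -2.09 ± 0.19, adjusted p 1.06e-06. Of the pDC markers 1 rose, 6 fell and 6 did not pass of 13 tested (1 and 8 over the list alone, camera adjusted p = 0.0016, 0.538 estimated), with Tcf4, a transcription factor of pDC, at -1.11 ± 0.21, adjusted p 0.00163. T cell markers gave 0 rises and 2 falls among 13 tested (0 and 2 over the list alone, camera adjusted p = 0.00138, 0.538 estimated), with a mean from 3.59 to 1.21 CPM. NK cell markers gave 0 rises and 6 falls among 11 tested (0 and 9 over the list alone, camera adjusted p = 0.00146, 0.538 estimated). Erythroid markers rose as a list (4 rises and 0 falls among 7 tested, 6 and 0 over the list alone). For the erythroid list the camera adjusted p was 0.0282 (0.558 estimated). That call was lost without KO library 1 (adjusted p = 0.0682) or KO library 3 (adjusted p = 0.107). MHC class II presentation gave 6 rises and 3 falls among 13 tested (6 and 3 over the list alone; camera adjusted p = 0.185). Monocyte markers gave 3 rises and 6 falls among 16 tested (camera adjusted p = 0.319) and red pulp macrophage markers 1 rise and 3 falls among 14 tested (camera adjusted p = 0.636). ADAM proteases and partners gave 3 rises and 5 falls among 20 tested (camera adjusted p = 0.331). For ADAM10 substrates the counts were 2 rises and 7 falls among 23 tested (camera adjusted p = 0.185), and for unfolded protein response genes 0 rises and 2 falls among 20 tested (camera adjusted p = 0.811).

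The overlap of the 3 effects was counted against chance. CD4+ and CD4-CD8- cells shared 1499 risen genes, where 361 would be met if the calls were independent, and 1062 fallen genes, where 251 would be. Another 33 rose in CD4+ and fell in CD4-CD8- cells (281 by chance), and 9 did the reverse (323 by chance), with a Pearson r of 0.547 between the log2 fold changes. CD4+ and CD8+ cells shared 483 risen (174 by chance) and 421 fallen genes (192 by chance). Another 254 genes rose in CD4+ and fell in CD8+ cells (215 by chance), and 117 fell in CD4+ and rose in CD8+ cells (155 by chance), with an r of 0.183. CD4-CD8- and CD8+ cells shared 501 risen (137 by chance) and 394 fallen genes (132 by chance). Another 188 rose in CD4-CD8- and fell in CD8+ cells (169 by chance), and 61 did the reverse (106 by chance), with an r of 0.286. Of genes changed at least 2-fold, 102 rose in CD4+ and fell in CD8+ cells (40.5 by chance). In both, 97 rose (13.0 by chance) and 141 fell (26.2). In CD4-CD8- cells 53 rose that fell in CD8+ cells (18.1). In all 3 populations 402 genes rose (25.3 by chance) and 315 fell (21.8). No library is shared between these comparisons. Same-numbered libraries of 2 populations still correlated within a genotype, for CD4-CD8- with CD8+ cells between 0.354 and 0.409 in KO and for CD4+ with CD8+ cells between 0.219 and 0.367 in WT. Part of the overlaps and of the r values may come from this shared noise, which the chance counts leave out. Genes are not independent either, so these counts are descriptive.

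**Figure D4:**
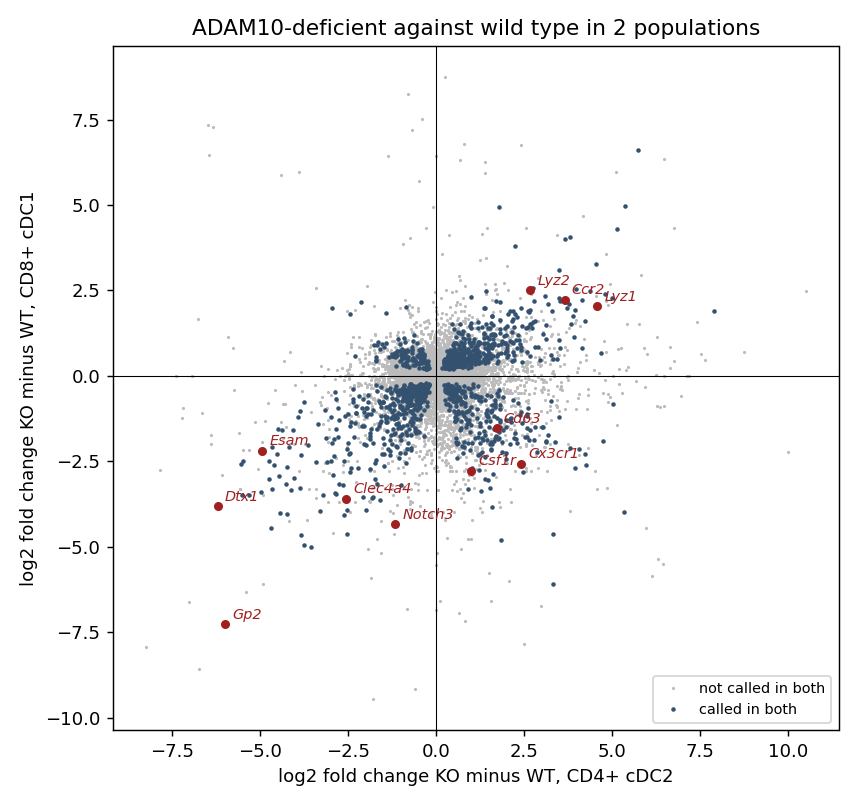
Log2 fold change (KO minus WT) of each tested gene in CD4+ cells against that in CD8+ cells, with 1 point per gene, dark where the gene was called in both and red where it is labelled. The values correlated with an r of 0.183.

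Interactions tested whether the signed KO effect differed between populations. Between CD4+ and CD8+ cells 2962 genes differed, 1685 with a higher and 1277 with a lower effect in CD4+ cells. With the length offset, the NK and T cell marker score as a covariate or 3 TPM scales (pseudocount of 1 or 0.1, or TMM-scaled), this count was 1427 to 1805. Fn1 (difference of log2 7.18 ± 1.16, adjusted p 0.000245) and Cxcl13 (7.29 ± 0.99, adjusted p 5.28e-05) were higher in this sense. Cdh17 (-5.34 ± 0.89, adjusted p 0.000323), Dhrs9, a retinol dehydrogenase (-4.29 ± 0.64, adjusted p 0.000125), and Gpr82 (-4.25 ± 0.59, adjusted p 6.8e-05) were lower. Klrb1a, an NK receptor, also differed (adjusted p = 0.00018), but had no count in KO CD8+ cells, so the size of its difference depends on the prior count. Its WT CD8+ mean (0.121 ± 0.0453 CPM) was 1.819 times a floor of 3 counts in KO, too near that floor for a lower bound. Between CD4-CD8- and CD8+ cells 1761 genes differed, 1102 with a higher and 659 with a lower effect in CD4-CD8- cells. With the offset, the TPM scales or without the WT libraries numbered 3, it was 774 to 1050, and on TPM with a pseudocount of 1 most were lower (429 higher and 533 lower). Hr, a nuclear corepressor (6.29 ± 0.46, adjusted p 4.09e-07), Cyp7b1, an oxysterol hydroxylase (4.90 ± 0.95, adjusted p 0.00237), and Ptgir, the prostacyclin receptor (4.82 ± 0.43, adjusted p 2.3e-06), were higher. Frmd5 was lower (-4.34 ± 0.35, adjusted p 8.2e-07). Between CD4+ and CD4-CD8- cells 503 genes differed, 332 with a higher and 171 with a lower effect in CD4+ cells. Dok2 was higher (6.29 ± 0.55, adjusted p 1.48e-05), and Gpr4, a proton-sensing receptor, lower (-2.54 ± 0.36, adjusted p 0.000652). The count of 503 was 17 with the covariate, where Gpr4 was at -1.86 (adjusted p = 0.211), and 150 to 258 with the offset, the TPM scales or without the WT libraries numbered 3.

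The WT populations differed from each other in 6106 genes between CD4+ and CD8+ cells, in 5738 between CD4-CD8- and CD8+ cells, and in 2241 between CD4+ and CD4-CD8- cells. With the covariate these were 3807, 2355 and 27, and on the TPM scales the last was 1111 to 1362. Trem1, a receptor that amplifies inflammation (log2 7.31 ± 0.79, adjusted p 9.65e-07), was higher in CD4+ than in CD8+ cells, and Gcsam, a signalling adaptor (log2 -10.39 ± 0.46, adjusted p 2.29e-11), lower. Tarm1, an activating receptor, was at least 238-fold higher in CD4+ than in CD8+ cells, where it had no count, and Dkk3, a Wnt modulator, was at least 566.8-fold lower. Mmp9 (log2 6.43 ± 0.40, adjusted p 2.47e-09) and Sirpb1c (log2 6.56 ± 0.36, adjusted p 6.14e-10) were higher in CD4-CD8- than in CD8+ cells, and Ptgis, prostacyclin synthase (log2 -7.10 ± 0.46, adjusted p 3.73e-09), lower. Between CD4+ and CD4-CD8- cells, the NK cell genes Klra8 (log2 -8.47 ± 0.56, adjusted p 1.48e-07), Klra4 (log2 -8.94 ± 0.61, adjusted p 7.6e-08) and Crtam (log2 -8.36 ± 0.64, adjusted p 1.91e-07) were lower in CD4+ cells, and Klk1, a kallikrein (log2 2.59 ± 0.55, adjusted p 0.00322), higher. Cd4 and Cd8a defined the gates and are no findings here. With the covariate Klra8 (log2 -5.55, adjusted p = 0.178), Klra4 (-5.98, 0.128), Crtam (-4.95, 0.101) and Klk1 (4.75, 0.495) did not pass. Klk1 also did not without the WT libraries numbered 3 (adjusted p = 0.0639).

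KO CD4+ cells were compared with the WT difference between CD4+ and CD4-CD8- cells. Of the 1288 genes lower in WT CD4+ than in WT CD4-CD8- cells, 696 (54.0%) rose in KO CD4+ cells, where 238 would by chance, and of the 953 higher ones 532 (55.8%) fell, where 158 would. The WT CD4+ libraries enter both comparisons, which brings a covariance of -0.0830 and an r of -0.492 in simulations without effects, against -0.358 and -0.393 observed. How much of these counts comes from the shared libraries was not determined. KO CD4-CD8- cells share no library with the WT difference between CD4+ and CD8+ cells. There 830 (27.0%) of the 3077 lower genes rose, where 449 would by chance, and 203 fell (349 by chance). Of the 3029 higher genes 736 (24.3%) fell, where 344 would by chance, and 435 rose (442 by chance), with an r of -0.216. KO CD8+ cells share none with the WT difference between CD4+ and CD4-CD8- cells. Of its 953 higher genes 241 (25.3%) fell, where 82.7 would by chance, and 105 rose (66.8 by chance). Of its 1288 lower genes 224 rose (90.3 by chance) and 208 fell (112 by chance), with an r of 0.0925.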

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

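Tests of explanations here were chosen after the results were seen, while library splits and interaction tests were planned. Of 107 genes named by size, by the fixed names or as the target, 67 had a KO effect that differed between populations in an interaction test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p). Of these, 66 are given below, each once. Of 204 genes named as list members, 129 differed. Values in parentheses are the difference in log2 units ± its standard error, then the adjusted p.

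A higher effect in CD4+ than in CD8+ cells was measured for Galnt9 (7.87 ± 1.4, 0.00102), Cxcl13 (7.29 ± 0.99, 5.28e-05), Pde2a (7.24 ± 2.2, 0.0288), Fn1 (7.18 ± 1.2, 0.000245), Cldn10 (6.85 ± 0.69, 2.96e-06) and Hr (6.66 ± 0.46, 5.65e-08). Also higher were Ptgir (6.53 ± 0.44, 4.63e-08), Alox5 (6.47 ± 1, 0.000239), Dok2 (6.44 ± 0.66, 3.05e-06), F13a1 (6.22 ± 1.2, 0.00146), Slc27a3 (5.98 ± 1.1, 0.000716) and Il1rl1 (5.83 ± 1.2, 0.0024). Next came Cd33 (5.41 ± 0.54, 2.21e-06), Cx3cr1 (4.99 ± 0.29, 1.8e-08), Dcstamp (4.45 ± 0.63, 7.8e-05), Mrc1 (4.39 ± 0.62, 7.9e-05), Lpl (3.91 ± 0.7, 0.000619) and Mab21l3 (3.46 ± 0.36, 4.35e-06). Then came Notch3 (3.18 ± 0.77, 0.00611), Plpp1 (2.90 ± 0.75, 0.00978), Gcsam (2.86 ± 0.81, 0.0168), Mgl2 (2.73 ± 0.79, 0.0199), Gpr141b (2.66 ± 0.55, 0.00203) and Lyz1 (2.54 ± 0.26, 3.47e-06). The same sign was found for Sirpa (2.22 ± 0.25, 9.03e-06), Dpep2 (1.91 ± 0.3, 0.000225), Notch1 (1.76 ± 0.22, 2.89e-05), Ccr2 (1.42 ± 0.15, 4.1e-06), Itgam (1.35 ± 0.31, 0.00446) and Cd8b1 (1.20 ± 0.35, 0.0214). The smallest were Cxcl16 (1.14 ± 0.23, 0.00145), Itgax (0.98 ± 0.14, 9.72e-05), Cd8a (0.95 ± 0.27, 0.0183) and Clec9a (0.54 ± 0.18, 0.038). Plpp1, Gcsam and Gpr141b held 0.49, 1.84 and 4.1 CPM in KO CD4+ but 65.5, 335 and 590 in KO CD8+ cells. Traces of cDC1 were not excluded.

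A lower effect in CD4+ than in CD8+ cells was measured for Zbtb46 (-0.66 ± 0.1, 0.00021), Cyp2s1 (-1.06 ± 0.28, 0.0115), S100a10 (-2.24 ± 0.28, 1.99e-05), Notch4 (-2.72 ± 0.37, 5.49e-05), Esam (-2.77 ± 0.4, 9.26e-05) and Sema4f (-2.92 ± 0.31, 5.37e-06). Next came Abcb1a (-2.96 ± 0.83, 0.0164), Blk (-3.00 ± 0.93, 0.0281), Gpr4 (-3.19 ± 0.34, 4.39e-06), Frmd5 (-3.36 ± 0.29, 5.29e-07), Fndc5 (-3.47 ± 0.72, 0.00215) and Ncald (-3.54 ± 0.73, 0.00205). The largest were Gpr161 (-3.95 ± 0.98, 0.00743), Gpr82 (-4.25 ± 0.59, 6.8e-05), Dhrs9 (-4.29 ± 0.64, 0.000125), Cltrn (-4.76 ± 1.1, 0.00773) and Cdh17 (-5.34 ± 0.89, 0.000323). Galnt9, Pde2a and Cltrn had no count in 1 group, so the fitted sizes depend on the prior count. Against a floor of 3 counts, Galnt9 was at least 1.09-fold and Pde2a at least 6.53-fold lower in KO than in WT CD8+ cells, and Cltrn at least 2.555-fold lower in KO than in WT CD4+ cells. Pde2a was not called in 5 of the 12 fits without 1 library, with adjusted p between 0.0206 and 0.0783.

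Between CD4-CD8- and CD8+ cells the effect was higher in the former for Cyp7b1 (4.90 ± 0.95, 0.00237), Apol7c (2.92 ± 0.29, 8.33e-06), Irf4 (2.74 ± 0.25, 2.85e-06), Adgrl3 (1.77 ± 0.42, 0.0101) and Clec4a4 (1.23 ± 0.39, 0.0464). It was lower in CD4-CD8- cells for Qpct (-1.75 ± 0.3, 0.000947), Btbd11 (-3.57 ± 0.81, 0.00731), Podnl1 (-4.80 ± 1.5, 0.0441) and Hist1h2ap (-6.96 ± 2.1, 0.0425). Hist1h2ap and Podnl1 each lost the call in 9 of the 12 fits without 1 library. Between CD4+ and CD4-CD8- cells the effect was higher in CD4+ cells for Igf2r (5.67 ± 0.33, 1.05e-07), Klrb1a (5.15 ± 0.52, 8.22e-05), Skap1 (5.01 ± 1.1, 0.0119) and Cd226 (4.92 ± 0.51, 6.46e-05). In the other direction stood Mmp9 (-1.96 ± 0.48, 0.0312) and Serpinb2 (-2.70 ± 0.48, 0.00414). Skap1 was at an adjusted p of 0.0668 without KO CD4+ library 3, and Mmp9 lost the call in 9 of the 12 fits without 1 library (adjusted p between 0.00237 and 0.088).

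After the results were seen, these 66 differences were run under the alternative fits (log2 difference, adjusted p). The sign turned, without a call, for Notch1 on TPM (-1.42, 0.419; with a pseudocount of 0.1 -1.49, 0.563), with the length offset (-1.25, 0.642) and on TMM-scaled TPM (-1.49, 0.38). It also turned for Adgrl3 on the same 3 TPM scales (-1.05, 0.217, then -0.479, 0.759 and -0.888, 0.304), for Clec4a4 on TPM (-0.464, 0.227) and TMM-scaled TPM (-0.277, 0.459), and for Gcsam on the latter (-0.13, 0.835). With the sign kept, the call was lost on TPM for Hist1h2ap (-6.13, 0.133), Igf2r (0.447, 0.755), Mmp9 (-0.859, 0.324), Serpinb2 (-0.673, 0.456), Pde2a (0.646, 0.256), Alox5 (1.11, 0.165), Plpp1 (0.41, 0.289), Gcsam (0.0306, 0.969), Gpr141b (0.698, 0.196), Itgax (0.747, 0.0713), Cyp2s1 (-0.536, 0.272), Esam (-2.2, 0.178), Sema4f (-1.05, 0.0834), Abcb1a (-3.27, 0.115), Fndc5 (-0.0438, 0.968) and Cltrn (-0.443, 0.417). With a pseudocount of 0.1 it was lost for 14 genes and on TMM-scaled TPM for 13. With the length offset it was lost for Adgrl3 (0.165, 0.947), Btbd11 (-3.03, 0.141), Podnl1 (-4.88, 0.0618), Hist1h2ap (-7.14, 0.0742), Mmp9 (-1.99, 0.463), Serpinb2 (-1.47, 0.16), Notch3 (3.82, 0.0514), Cd8b1 (1.19, 0.0647), Cyp2s1 (-1.07, 0.31), Esam (-1.58, 0.438) and Abcb1a (-1.61, 0.81). With the NK and T cell marker score as a covariate it was lost for Clec4a4 (1.21, 0.0757), Podnl1 (-4.62, 0.075), Klrb1a (4.76, 0.114), Skap1 (1.31, 0.803), Mmp9 (-2.2, 0.575), Serpinb2 (-2.2, 0.372), Pde2a (7.73, 0.0815), Mgl2 (2.2, 0.105), Cd8a (0.699, 0.176), Clec9a (0.536, 0.179), Cyp2s1 (-0.847, 0.165), Blk (-2.73, 0.109) and Gpr161 (-3.43, 0.0854). Without the WT libraries numbered 3 it was lost for Adgrl3 (1.57, 0.061), Clec4a4 (1.07, 0.164), Podnl1 (-6.81, 0.0762), Hist1h2ap (-8.79, 0.0612), Skap1 (5.03, 0.057), Mmp9 (-1.85, 0.13), Pde2a (6.82, 0.118), Gcsam (3.06, 0.0645), Itgam (0.998, 0.0603), Cd8b1 (1.17, 0.0795), Cd8a (0.948, 0.0675), Clec9a (0.53, 0.124) and Blk (-2.71, 0.0706). A replicate block by number ended the call of Clec4a4 (1.22, 0.055) and Hist1h2ap (-6.56, 0.0601), and a block by genotype and number that of Podnl1 (-4.9, 0.056). Fits on the compared groups only ended that of Clec4a4 (1.22, 0.0592) and Mmp9 (-1.93, 0.0549), the filter of 5 CPM that of Podnl1 (-4.8, 0.0538), and DESeq2 that of Hist1h2ap (-6.97, 0.0791). Of the 12 fits without 1 library each, the call was lost (highest adjusted p in parentheses) for Clec4a4 in 9 (0.179 without KO CD8+ library 1), Gcsam in 2 (0.0697 without KO CD4+ library 2), Mgl2 in 1 (0.0999 without WT CD8+ library 1), Cd8b1 in 6 (0.0624 without WT CD8+ library 3), Cd8a in 2 (0.112 without KO CD4+ library 2), Clec9a in 8 (0.109 without KO CD4+ library 3), Abcb1a in 1 (0.316 without KO CD8+ library 3) and Blk in 2 (0.166 without KO CD8+ library 3).

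In KO CD4+ cells 13 of 13 ESAM-low genes rose (camera adjusted p = 5.59e-11, but 0.0926 estimated). The monocyte list did not pass (9 rises and 5 falls among 16, camera adjusted p = 0.162, but fry adjusted p = 2.44e-06). Monocytes added to unchanged cDC2 would lower no monocyte marker, but 5 of 16 (31.2%) were at least 2-fold lower (pan-cDC list median 0.07). This argues against that case only, not against monocytes beside changed cDC2. Of the 16 markers 4 are in another list and 14 reached 5 CPM in a WT population. The MHCII gate should remove most monocytes. A WT subset that became the majority in KO could hold at most 3.04% of WT CD4+ cells by Clec10a, lowest of the ESAM-low list. Outside that list Fn1 gave 0.491% and Fcrls 0.0598%. Such a subset, added macrophages (10 of 14 red pulp markers rose, 1 fell) and changed expression within cells cannot be separated without cell numbers.

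In KO CD8+ cells 13 of 19 genes of the cDC2 list fell (camera adjusted p = 3.02e-10, but 0.0821 with an estimated correlation). If cDC2 had been mixed into the WT CD8+ gate, their largest allowed share was 2.15% of CD4-CD8- cells (set by Clec4a3) or 1.24% of CD4+ cells (set by Cd4). The share allowed by the list accounted for a median of 9.1% of the WT level of the 13 fallen members, with a highest value of 84.9%. This argues against such a mixture as the whole cause of the fall of these members. Loss of a CX3CR1+ and pDC-like fraction of CD8+ cells may also lower them, and the pDC list median was -0.454. It cannot be told apart from lower expression within all CD8+ cells.

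NK and T cell transcripts fell in KO CD4-CD8- cells, where 20 of the 24 markers tested (83.3%) were lower in KO, with a median log2 of -2.57 and an SD of 0.839. That count restates the fall, so the source of the transcripts, lymphocytes in the WT gate or other cells, was not determined. None of the 24 is held by another list, 22 reached 5 CPM in a WT population, and the CD11c and MHCII gate should remove resting T cells but not every NK cell. Transcripts restricted to WT CD4-CD8- cells made up 170 of the 578 genes at least 2-fold lower (29.4%), but only 281 such transcripts were tested, so that share cannot decide whether most of the falls came from them.

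Other splits of the same libraries were counted for each comparison. For comparisons of 6 libraries there are only 10 splits, too few to decide: the real split called 4692 (CD4+), 3471 (CD4-CD8-) and 2099 (CD8+) genes, each the largest (1 of 10), against a highest other of 0. Between WT populations the real counts of 6106, 5738 and 2241 were also 1 of 10, with a highest other of 0, 0 and 2. For the interactions 4 of 100 splits called as many genes each. The real counts were 2962, 1761 and 503 and the highest others 3779, 6776 and 2250, and each of the other 3 splits as large put at least 5 of the 6 libraries of 1 population or genotype on 1 side.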

How the results depend on the processing

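Tests chosen after the data were seen were the covariate (NK and T cell marker score), leaving out the 3 WT libraries numbered 3, limma on TMM-scaled TPM, and the fits behind the overlap and axis counts. Under all alternatives 8228 values of named genes kept their direction and side of the threshold, 667 lost the call, 6 gained one and 26 reversed; for lists these were 1134, 50, 35 and 2. A change of sign between values that both missed the threshold was not counted. DESeq2's Wald test called 4751, 3598 and 2283 genes in CD4+, CD4-CD8- and CD8+ cells, and DESeq2 size factors 4704, 3477 and 2102. Quantile normalization, planned for files without counts, was not run.

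The counts of KO minus WT moved most on TMM-scaled TPM in CD4+ cells and with the covariate in CD4-CD8- and CD8+ cells. In CD4+ cells they were 3098 and 3074 with limma on TPM (pseudocounts of 1 and 0.1), 3097 with a length offset and 2838 on TMM-scaled TPM. In CD4-CD8- cells they were 2179 with the offset, 934 with the covariate and 2166 on TMM-scaled TPM, and in CD8+ cells 1395, 1178 and 1194, with 1389 without the WT libraries numbered 3. For the interaction of CD4+ and CD8+ cells the counts were 1437, 1427, 1805 (offset), 1731 (covariate) and 1710 (TMM-scaled TPM). For CD4-CD8- and CD8+ cells they were 962, 774, 903 (offset), 954 (without WT libraries 3) and 1050 (TMM-scaled TPM). For CD4+ and CD4-CD8- cells they were 255, 150, 193 (offset), 17 (covariate), 254 (without WT libraries 3) and 258 (TMM-scaled TPM). Between WT populations the counts were 3986, 4021 and 3807 (covariate) for CD4+ and CD8+ cells, 2355 (covariate) and 3800 (TMM-scaled TPM) for CD4-CD8- and CD8+ cells, and 1362, 1301, 1264 (offset), 27 (covariate), 1152 (without WT libraries 3) and 1111 (TMM-scaled TPM) for CD4+ and CD4-CD8- cells. Apart from the fewer samples, the cause was not tested. The score nearly labels the CD4-CD8- groups and is made from genes that are tested.

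Without 1 library the counts ran from 3930 to 4347, 2669 to 3086 and 1527 to 2060 for KO minus WT, from 2497 to 2963, 1330 to 1720 and 306 to 549 for the interactions, and from 5306 to 5691, 4812 to 5330 and 1517 to 2032 between WT populations. The lowest counts for CD4+ and CD4-CD8- cells were 306 without WT CD4+ library 2, 312 without WT CD4-CD8- library 1, 318 without KO CD4+ library 3 and 330 without KO CD4-CD8- library 2.

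On unscaled TPM 32.0%, 17.1% and 15.5% of the calls in CD4+, CD4-CD8- and CD8+ cells were higher in KO, against 52.8%, 56.3% and 44.7% on counts, and the median of all genes moved to -0.118, -0.211 and -0.151. On TMM-scaled TPM the shares were 53.7%, 55.5% and 47.7%, so the shift came from the absence of composition scaling. Between WT CD4+ and CD4-CD8- cells 42.5% of calls were higher in CD4+ cells, 30.4% without WT libraries 3 and 3.70% with the covariate.

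With a replicate block by number, 4971, 3808 and 2339 genes were called for KO minus WT, 3221, 1985 and 582 for the interactions and 6366, 6008 and 2489 between WT populations. With a block by genotype and number the interactions had 3544, 2269 and 850 and the WT populations 6606, 6278 and 2850. All 18 libraries correlated best with their own number (mean 0.273), a hint from the data, not the design. The block by number left the cDC1 list in CD4-CD8- cells at an adjusted p of 0.0529, the erythroid list in CD4+ cells at 0.00934, and Irf4 at 0.0440 in CD4+ and 0.0419 in CD4-CD8- cells. The blocks ended the call of Clec4a4, Hist1h2ap and Podnl1 between CD4-CD8- and CD8+ cells and of no other of the 66 differences listed. For the interactions and WT differences whose numbers pair the libraries, no count moved by over 1.5 times.

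Reversed values follow, as log2. In CD4-CD8- cells, with limma on TPM at pseudocounts of 1 and 0.1, Cd4 was at 0.17 and 0.22 (0.44 with the offset, 0.37 on TMM-scaled TPM), Zbtb46 at -0.31 and -0.34, Csf2rb at -0.31 and -0.31 (-0.0295 and -0.0417), Tapbp at -0.0805 and -0.0808, Aph1a at -0.0800 and -0.0807, and Gpi1 at -0.0037 and -0.0037. With the covariate Lck was at 0.23 and Trbc1 at 0.12, and Gzma between WT CD4+ and CD4-CD8- cells at 0.46. In CD8+ cells Notch1 was at 2.48, 2.99 and 2.66 (TMM-scaled TPM), and Sel1l at 0.0309 with the offset and 0.0277 on TMM-scaled TPM. Alox5 differed between CD4+ and CD4-CD8- cells by -0.0773 on TPM and -0.23 on TMM-scaled TPM. The T cell list, part of the score, reversed with the covariate (adjusted p 0.91 in CD4-CD8- and 0.611 in CD8+ cells). Other causes were not tested.

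With an estimated correlation 0, 0 and 0 lists were called, from 10, 13 and 13. At a 2-fold threshold the shared risen and fallen genes were 357 and 285 (CD4+ and CD4-CD8- cells), 97 and 141 (CD4+ and CD8+) and 67 and 171 (CD4-CD8- and CD8+), fewer by construction. Those that rose in the first and fell in the second were 21, 102 and 53, and 0, 5 and 2 did the reverse. With the covariate the shared counts were 488 and 337, 257 risen, and 141 and 173. Without WT libraries 3, 289 and 266 risen genes were shared with CD8+ cells by CD4+ and CD4-CD8- cells. With the covariate, of the 27 genes left between WT CD4+ and CD4-CD8- cells, 1 was higher and 26 lower. Of these 0% of the higher fell and 88.5% of the lower rose in KO CD4+ cells, and 0% of the higher fell in KO CD8+ cells, too few for a comparison. Along the WT difference of CD4+ and CD8+ cells, 11.2% of the higher fell and 12.2% of the lower rose in KO CD4-CD8- cells.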

Other observations

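Of what follows, only the test of variants around Adam10 was chosen after the result was seen. Where 3 values follow each other, they are for CD4+, CD4-CD8- and CD8+ cells in this order. Rises and falls are counted among the genes tested, and the adjusted p of a list is that of camera. Inflammatory mediators gave 5 rises and 3 falls among 19 in CD4+ cells (6 and 3 over the list alone; adjusted p = 0.298), 7 rises and 3 falls among 19 in CD4-CD8- cells (adjusted p = 0.0676, passed without WT library 1 (0.0377), WT library 2 (0.0244) or KO library 1 (0.0227)) and 3 rises and 4 falls among 19 in CD8+ cells (adjusted p = 0.167). The chemokine genes Ccl6 (log2 4.14 ± 0.24, adjusted p 2.07e-09) and Ccl9 (log2 3.58 ± 0.24, adjusted p 8.85e-09) rose in CD4+ cells, and Il12b, the shared chain of IL-12 and IL-23, fell there (log2 -1.61 ± 0.31, adjusted p 0.000601). Glycolysis genes gave 6 rises and 1 fall among 16 in CD4+ cells (6 and 1 over the list alone; adjusted p = 0.0596, passed without KO library 3 (0.0217)) and 2 rises and 1 fall among 16 in CD8+ cells (adjusted p = 0.543). In CD4-CD8- cells 6 rose, 0 fell and 10 did not pass of 16 tested, the list's camera adjusted p was 0.0187 (0.538 with an estimated correlation), and without KO library 1 it was 0.059. Pfkp, a phosphofructokinase, rose in CD4+ cells (log2 1.57 ± 0.14, adjusted p 1.41e-07). Migration and adhesion receptors gave 8 rises and 6 falls among 23 (adjusted p = 0.338), 8 rises and 7 falls among 23 (adjusted p = 0.811) and 5 rises and 11 falls among 23 (adjusted p = 0.0763, passed without KO library 3 (0.0216)) in the 3 populations. Toll-like and C-type lectin receptors gave 12 rises and 6 falls among 26 in CD4+ (adjusted p = 0.0584, passed without KO library 2 (0.0197)) and 3 rises and 10 falls among 26 in CD8+ cells (adjusted p = 0.0583, passed without KO library 3 (0.0137)).

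Genes of MHC class I presentation gave 4 rises and 1 fall among 16 in CD4+ (adjusted p = 0.977), 4 rises and 0 falls among 16 in CD4-CD8- (adjusted p = 0.363) and 0 rises and 0 falls among 16 in CD8+ cells (adjusted p = 0.58). For interferon-stimulated genes the values were 4 rises and 6 falls among 27 in CD4+ (adjusted p = 0.585) and 5 rises and 3 falls among 27 in CD4-CD8- cells (adjusted p = 0.338, passed without WT library 2 (0.0394)). Cholesterol synthesis gave 5 rises and 5 falls among 20 (adjusted p = 0.963), 4 rises and 1 fall among 20 (adjusted p = 0.387) and 2 rises and 0 falls among 20 (adjusted p = 0.909). LXR targets gave 4 rises and 1 fall among 10 in CD4+ (adjusted p = 0.267) and 2 rises and 2 falls among 10 in CD4-CD8- cells (adjusted p = 0.71), with Abca1, a cholesterol transporter, at log2 2.24 ± 0.31, adjusted p 2.29e-05 in CD4+ cells. Oxidative phosphorylation gave 1 rise and 3 falls among 28 (adjusted p = 0.754), 2 rises and 0 falls among 28 (adjusted p = 0.391) and 2 rises and 0 falls among 28 (adjusted p = 0.58, passed without KO library 3 (0.0181)), and immediate early genes 5 rises and 2 falls among 27 (adjusted p = 0.801), 5 rises and 0 falls among 27 (adjusted p = 0.58) and 0 rises and 1 fall among 27 (adjusted p = 0.318, passed without KO library 2 (0.00328)).

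Markers of further cells were also counted. B cell markers gave 1 rise and 4 falls among 13 (adjusted p = 0.363) and NK cell markers 1 rise and 0 falls among 11 (adjusted p = 0.971) in CD4+ cells. Plasma cell markers gave 0 rises and 0 falls among 5 (adjusted p = 0.689), 0 rises and 0 falls among 5 (adjusted p = 0.319) and 0 rises and 0 falls among 5 (adjusted p = 0.388). For pDC markers the counts were 5 rises and 1 fall among 13 in CD4+ (adjusted p = 0.221) and 5 rises and 1 fall among 13 in CD4-CD8- cells (adjusted p = 0.136, passed without WT library 1 (0.0488)). Marginal zone macrophage markers gave 2 rises and 0 falls among 4 (adjusted p = 0.17), 1 rise and 0 falls among 4 (adjusted p = 0.269) and 0 rises and 0 falls among 4 (adjusted p = 0.269), with Siglec1, the sialoadhesin gene, at log2 2.70 ± 0.42, adjusted p 9.03e-05 in CD4+ cells. Erythroid markers gave 5 rises and 0 falls among 7 in CD4+ (adjusted p = 0.0601, passed without WT library 3 (0.0477) or KO library 2 (0.0116)) and 1 rise and 1 fall among 7 in CD4-CD8- cells (adjusted p = 0.636).

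Neutrophil markers gave 0 rises and 1 fall among 3 (adjusted p = 0.396), 0 rises and 1 fall among 3 (adjusted p = 0.221) and 0 rises and 0 falls among 3 (adjusted p = 0.363). Platelet markers gave 1 rise and 0 falls among 3 (adjusted p = 0.331), 0 rises and 0 falls among 3 (adjusted p = 0.58) and 0 rises and 0 falls among 3 (adjusted p = 0.65). Stromal and endothelial markers gave 2 rises and 0 falls among 6 (adjusted p = 0.126), 1 rise and 0 falls among 6 (adjusted p = 0.363) and 0 rises and 2 falls among 6 (adjusted p = 0.0537, passed without WT library 2 (0.043) or KO library 3 (0.0374)). Of the mast cell and basophil markers 1 was tested, Cd200r3, which rose in CD4-CD8- cells (log2 2.38 ± 0.54, adjusted p 0.00344, but 2.70 at an adjusted p of 0.0811 with the NK and T cell marker score as a covariate). Mitochondrially encoded genes gave 0 rises and 0 falls among 13 (adjusted p = 0.53), 1 rise and 0 falls among 13 (adjusted p = 0.284, passed without KO library 1 (0.0223)) and 0 rises and 0 falls among 13 (adjusted p = 0.273).

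Replicates of KO and WT did not overlap for 6241 genes (46.6%) in CD4+, 5649 (42.2%) in CD4-CD8- and 3953 (29.5%) in CD8+ cells, where 10% would by chance. Between WT populations these were 7565 (56.5%), 7268 (54.3%) and 4954 (37.0%).

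As a hypothesis, passenger variants around Adam10 on chromosome 9 could account for some genes called in the same direction in all 3 populations. Of the 110 genes tested within 10 Mb of it besides Adam10, 6 (5.45%) were called so, namely Lysmd2, Anxa2, Cln6, Rpl4, Ints14 and Eef1a1, against 5.35% of the other genes (Fisher exact test, one-sided p = 0.54). No excess was found near Adam10, and a small one would be missed.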
